A study of Caenorhabditis elegans with 4 samples.

How the data were processed

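Synchronized hermaphrodites were raised at 20 degrees Celsius to L2 and fixed in 2% formaldehyde, and their sonicated chromatin was immunoprecipitated with antibodies against GFP, per the labels' protocols. A part of each supernatant was kept as input. The labels place the 4 samples in 2 groups of 2, ChIP and input, by their titles. One peak list per ChIP replicate and 1 combined list were used. The input samples had no list and are not analysed here.

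Per the file headers, the lists are in GFF version 3 on WormBase build WS220. The source column of every deposited peak names the SPP peak caller and IDR, a method that ranks peaks by their reproducibility between replicates. The aligner, the tool versions, the threshold of each list, how the input was used and how the replicates were combined are not given in the sources used here. Each deposited peak carries the authors' score, whose scale is not stated. The score is used only to rank or filter peaks within a list and, over pairs of overlapping peaks, in a correlation between lists. It is never read as a size of binding. The number in each peak's name runs once from 1 to the length of its list and mostly rises as the score falls (Spearman rho of -0.999 in replicate 1, -0.99 in replicate 2 and -0.78 in the combined list, where 73.2% of peaks share the highest score). Peaks were ranked by score, with ties in the order of this number. The order is not strictly the same: in replicate 1 the median score was 3.36 for peak numbers 3001 to 3500 and 3.50 for numbers 4501 to 5000. Read depth cannot be recovered from these lists, so precision is given only as counting error of peaks.

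From the lists, peak numbers, widths, covered lengths and densities were computed. Chromosome lengths were taken as the largest peak end over the 3 lists, 100.2 Mb for the 6 nuclear chromosomes. Peaks were called overlapping when they shared at least 1 bp. Chance overlap came from 1000 circular shifts, with 1 random offset per chromosome, which keep the number, width and spacing of peaks. The lists compared at equal length were the 6494 highest-scoring peaks of each replicate, the length of the combined list. Scores were correlated over one-to-one overlapping pairs with 100000 resamples. Going down the ranks of replicate 1, each peak took its best-scoring free partner in replicate 2. Densities on X and in the middle 33.3% of the autosomes were tested with exact binomial tests against the share of length, and intervals for shares are exact 95% Clopper-Pearson intervals. The p-values of the 11 main tests were adjusted by the Benjamini-Hochberg method. With 2 replicates no test between samples was made, and p-values describe peaks within these lists. Peaks are not independent of each other, so the binomial and Fisher p-values cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

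The steps were tested on simulated lists. For the overlap, 20 runs of 5000 peaks per list with 30% planted shared peaks gave a mean of 30.0% above chance, and all 20 were called. With no shared peaks 0 of 20 were called. For the density on X, 20 runs of 6000 peaks with a planted ratio of 1.3 gave a mean of 1.31 and 20 calls, and with a ratio of 1 there was 1 call. For the scores, 20 runs of 2000 pairs with a planted correlation of 0.5 gave a mean of 0.50 and 20 calls, and with no correlation there was 1 call. The simulated peaks were placed independently and uniformly at random, and their scores had no ties. The runs therefore do not show how the tests behave on clustered peaks or tied scores, as in the deposited lists.

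The tests, samples and alternatives were fixed before the data were examined, except those named as chosen later. The alternatives were a 50% reciprocal overlap, midpoints within 200 bp, merging of overlapping peaks, the upper 50% of a list, peaks found in both replicates, each replicate alone, and other definitions of the chromosome centre. The rule for the peaks named, also fixed beforehand, was the 10 highest-scoring combined peaks that overlap a peak in both replicates. As 4754 combined peaks share the highest score, the peak number alone decided which 10 these are. Tests of peaks near gene starts, of gene lists and of the transgene loci were planned only for the case that an annotation of the same build was at hand. The gene table used here belongs to assembly WBcel235, so these tests were not run and no gene is named beside a peak.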

Results

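The binding of C34F6.9 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in L2 larvae of *Caenorhabditis elegans*, a nematode worm whose second larval stage is called L2. The hermaphrodites came from strain OP324, which carries a transgene encoding C34F6.9 fused to green fluorescent protein (GFP), and the fusion protein was collected with antibodies against GFP. The study set out to locate the genomic regions bound by the fusion protein. The 4 samples form 2 groups, 2 ChIP samples and 2 input samples of total genomic DNA. A list of peaks was analysed for each ChIP sample, together with 1 combined list. The input samples had no list of their own and are not analysed here, so the background in them is not given beside the peaks. The lists hold no read counts, so sequencing depth is unknown. The labels do not say whether the replicates came from separate cultures. All positions are in WormBase build WS220. The gene table at hand belongs to another build, so peaks are named by position and no gene is assigned to them.

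ChIP replicate 1 held 29725 peaks covering 11.996 Mb, replicate 2 held 23374 peaks covering 9.69 Mb, and the combined list held 6494 peaks covering 2.47 Mb, or 2.46% of the genome. The combined peaks lay on all 6 nuclear chromosomes and none lay on the mitochondrial genome. Most peaks had 1 fixed width. In replicate 1, 95.2% of peaks were 450 bp wide, in replicate 2, 94.9% were 460 bp wide, and in the combined list 67.3% were 456 bp wide. High-ranked peaks were narrower, with a median width of 267 bp in the top 500 of replicate 1, 284.5 bp in the top 500 of replicate 2 and 338 bp in the top 500 of the combined list. In the combined list the narrowest peaks came just after the first ranks: the median width was 324 bp in the first 10% of the list, 237 bp in the next 10%, 216 bp in the 10% after that and 456 bp further down. The authors' score reached its highest value in 4754 combined peaks, which is 73.2% of that list, so the number in the peak's name was used to order tied peaks.

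Combined peak number 1 lay on chromosome II at 10563315 to 10563740, and it was also number 1 in both replicates. Number 2 was on chromosome III at 3867362 to 3867759, also number 2 in replicate 1 and number 3 in replicate 2. Number 3 was on chromosome IV at 4749850 to 4750253, number 8 in replicate 1 and number 2 in replicate 2. Chromosome II held another of the first 10 peaks, at 8787317 to 8787757. Chromosome III held 3 more, at 7854406 to 7854825, at 9765318 to 9765833 and at 10758917 to 10759416. Chromosome I held 2, at 9625874 to 9626251 and at 6564448 to 6564813. Chromosome V held 1, at 9546771 to 9547176, and chromosome X held none of the 10. These 10 peaks were between 366 and 516 bp wide. Each was found among the first 16 peaks of replicate 1 and the first 24 peaks of replicate 2. All 10 had the highest score of the combined list, 3.50, which 4754 peaks share, so both their selection and their order rest on the peak numbers.

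Whether the same regions were called in both replicates was examined by the overlap of the 2 lists. Nearly all top-ranked regions of one replicate recurred somewhere in the full list of the other, and fewer recurred among its own top-ranked regions. Of the 6494 highest-scoring peaks of replicate 1, 5216 (80.3%, exact 95% interval 79.3 to 81.3%) shared at least 1 bp with one of the 6494 highest-scoring peaks of replicate 2, against a mean of 5.37% in 1000 circular shifts of the latter along the chromosomes. In the opposite direction 5269 peaks (81.1%, 80.2 to 82.1%) overlapped, against 5.43%. With only the 3247 highest-ranked peaks of each list, the shares were 65.8% and 67.1%. In the full lists, 58.6% of replicate 1 peaks and 71.8% of replicate 2 peaks overlapped a peak of the other, against 18.3% and 22.7% in shifted lists. None of the 1000 shifts reached the observed overlap in any of these comparisons (one-sided permutation p = 0.001, the smallest these shifts can give, and 0.0011 after Benjamini-Hochberg adjustment over 11 tests, which do not include the lists of 3247 peaks). Of the first 1000 peaks by rank, counting nuclear chromosomes, 99.9% of those in replicate 1 and 99.7% of those in replicate 2 overlapped the full list of the other. Between ranks 10001 and 11000 the shares were 69.3% and 74.2%. Beyond rank 28000 in replicate 1 and beyond rank 22000 in replicate 2 they were 31.2% or less and 43.8% or less, which was still above the shifted lists.

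**Figure D1:**
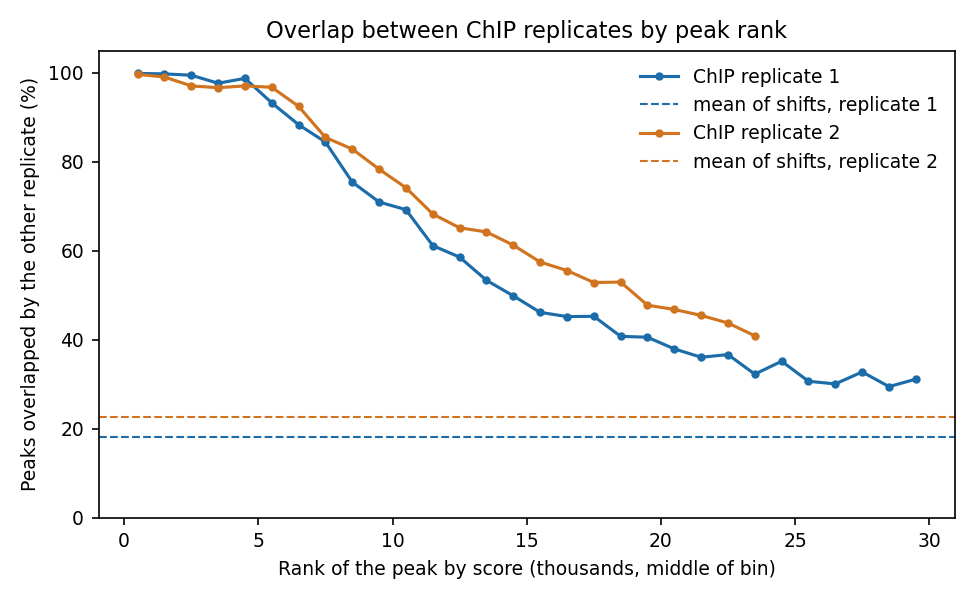
Share of the peaks of each ChIP replicate that overlapped a peak of the other replicate by at least 1 bp (y axis, percent), in bins of 1000 ranks by score (x axis, in units of 1000 ranks), nuclear chromosomes only. Points are bins, and dashed lines are the means of 1000 circular shifts over the whole list, 18.2% for replicate 1 and 22.6% for replicate 2; both curves start above 99% and fall without reaching their dashed line.

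Regions that scored high in one replicate also tended to score high in the other. Over 15044 pairs of overlapping peaks, the authors' scores had a Spearman rho of 0.74 and a Pearson r of 0.76 (permutation p = 1e-05 for each, two-sided, the smallest that 100000 resamples can give, adjusted p = 3.7e-05). These correlations run across peaks, which are not independent replicates. Where a peak had more than 1 possible partner, the pair was chosen by score, which can raise the correlation. The resamples shuffled scores after the pairing, so the p-values do not allow for this choice. Among the 6891 pairs that overlapped a combined peak, rho was 0.53 and r was 0.45. Among the 7522 pairs with the higher mean ranks, rho was 0.51 and r was 0.30.

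The combined list was then compared with each replicate. Nearly every combined region was present in both: 6456 of 6494 peaks (99.4%, exact 95% interval 99.2 to 99.6%) overlapped a peak in both replicates, against 11.3% in shifted lists (one-sided permutation p = 0.001, adjusted p = 0.0011). Replicate 1 lacked 21 combined peaks, replicate 2 lacked 17, and no combined peak was absent from both. Of the 6494 highest-scoring peaks of each replicate, 90.6% in replicate 1 and 89.1% in replicate 2 overlapped a combined peak. As the combined list was made from the same samples, this overlap is not independent evidence of binding. Its boundaries were set anew, since no combined peak had the same start and end as a peak of either replicate.

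The chromosomes differed in their density of combined peaks, which is given without an input list or gene annotation beside it. Chromosome III carried 81.7 combined peaks per Mb (exact Poisson 95% interval 77.0 to 86.6) and chromosome I carried 80.4 (75.9 to 85.0). Chromosomes X and II followed with 67.0 (63.2 to 70.9) and 66.7 (62.6 to 70.9), and chromosome IV had 58.3 (54.7 to 61.95). Chromosome V was the sparsest with 44.6 (41.8 to 47.6). Chromosome III also held 120 of the 500 highest-ranked combined peaks (24%, 20.3 to 27.99%), while it makes up 13.7% of the nuclear length. Chromosome I held 101 of them (20.2%, 16.8 to 23.99%) for 15.02% of the length, and chromosome V held 68 (13.6%, 10.7 to 16.9%) for 20.9%. The intervals cover counting error only, and neighbouring peaks are not independent.

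In the combined list, chromosome X as a whole was not distinguishable from the autosomes in peak density. It held 1187 of the 6494 combined peaks, or 18.3% for 17.7% of the length, which gives a density 1.04 times that of the autosomes (95% interval 0.98 to 1.11, exact binomial test, two-sided, p = 0.20, adjusted p = 0.20). Its density lay within the range of the 5 autosomes. In the full replicate lists, which reach to lower scores, X held a larger share, 20.9% of nuclear peaks in replicate 1 and 21.4% in replicate 2. It had 350 peaks per Mb in replicate 1 (exact Poisson 95% interval 341 to 358), next to 348 on chromosome III (339 to 358). In replicate 2 it had 282 (274 to 290), and III had 263 (254 to 272). The combined result depended on rank. The division into 3247 higher-ranked and 3247 lower-ranked peaks falls within the 4754 peaks that share the highest score, so it rests on the peak number alone. Among the 3247 higher-ranked combined peaks X was the sparser, with 485 of them (14.9%) and a density ratio of 0.82 (0.74 to 0.90, exact binomial p = 3.1e-05). Among the 3247 lower-ranked peaks it was the denser, with 702 of them (21.6%) and a ratio of 1.28 (1.18 to 1.40, exact binomial p = 9.8e-09). The lower-ranked peaks were examined only after the higher-ranked ones had been seen.

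**Figure D2:**
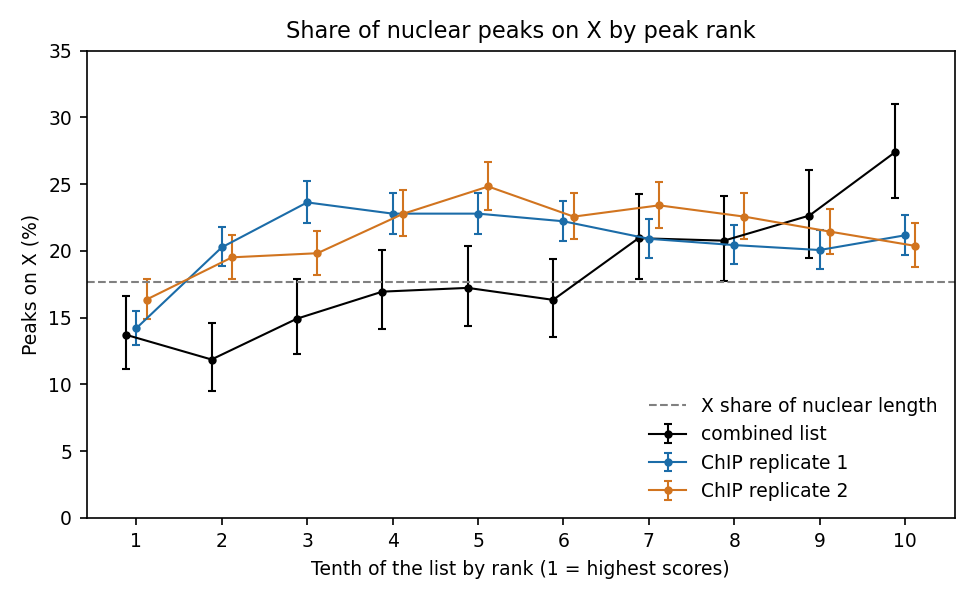
Share of nuclear peaks that lay on X (y axis, percent) in 10 equal steps of rank through the combined list and the 2 ChIP replicate lists (x axis, step 1 is ranked highest; steps 1 to 7 of the combined list have the same median score, so their order follows the peak number). Bars are exact 95% binomial intervals and the dashed line is the X share of the nuclear length, 17.7%; in the combined list the X share was 13.7% in step 1 and 27.4% in step 10, while in replicate 1 it was 14.2% in step 1, 23.6% in step 3 and 21.2% in step 10, and in replicate 2 it was 16.4% in step 1, 24.8% in step 5 and 20.4% in step 10.

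Along each autosome, the combined peaks were concentrated in the central part, compared with even spacing by length. The centres were examined because those of C. elegans autosomes are gene-rich. No input list or gene annotation was at hand, so how far the concentration follows gene density was not tested. The middle 33.3% of the length of the autosomes held 2416 of their 5307 combined peaks (45.5%, exact 95% interval 44.2 to 46.9%), or 87.8 peaks per Mb against 52.6 in the outer parts. The density ratio was 1.67 (1.58 to 1.76, exact binomial test, two-sided, p = 1.5e-75, adjusted p = 1.6e-74). All 5 autosomes showed it, from 41.6% of peaks on chromosome III (38.7 to 44.5%) to 47.97% on chromosome V (44.7 to 51.2%). On chromosome V the middle part carried 64.2 peaks per Mb and the outer parts 34.8, and on chromosome I the values were 112.0 and 64.6. The direction did not hold for the lowest ranks of replicate 1, where the middle part held 28.7% (26.9 to 30.6%) of autosomal peaks in the last 10% of the list, below its share of the length. In the last 10% of replicate 2 it held 36.7% (34.5 to 38.9%). Chromosome II was also uneven at its ends, with 40.7 peaks per Mb in the left part and 63.4 in the right. Chromosome X differed from the autosomes: its middle part held 391 of 1187 peaks (32.9%, 30.3 to 35.7%), close to the share of the length (Fisher's exact test against the autosomes, two-sided, odds ratio 0.59, p = 1.7e-15, a test chosen after the counts per chromosome were seen).

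**Figure D3:**
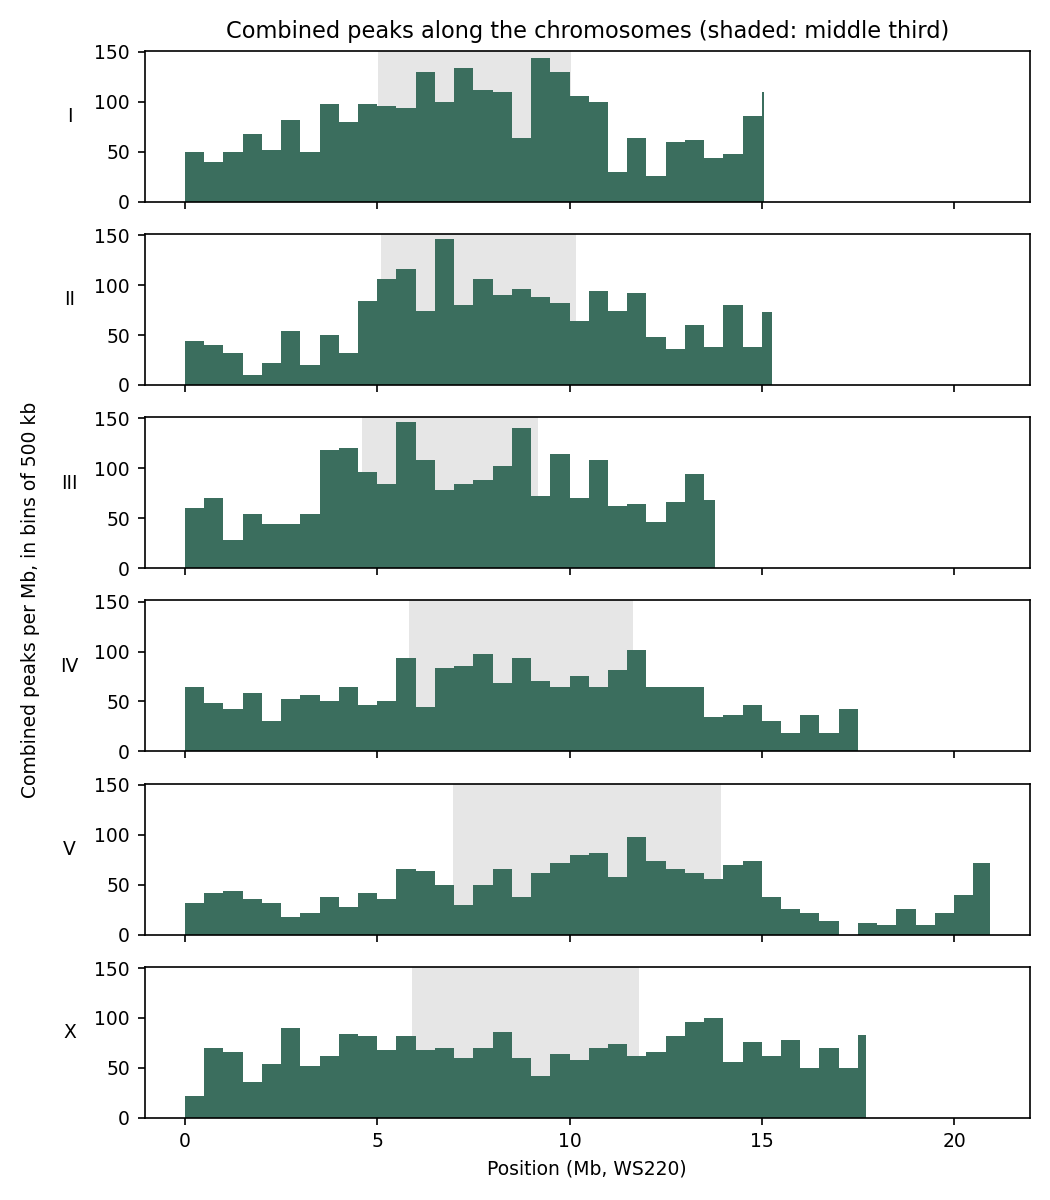
Combined peaks per Mb (y axis) in bins of 500 kb along the 6 nuclear chromosomes (x axis, Mb in WS220), with the middle part of each chromosome shaded. On the autosomes the bins are highest in or next to the shaded part, where density averaged 87.8 peaks per Mb, while on X the middle part had 66.2 and the outer parts 67.4.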

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

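The tests in this part were chosen after the mitochondrial peaks had been seen, and their criteria were also written afterwards. The mitochondrial genome, which the density comparisons leave out, carried 24 peaks in ChIP replicate 1 and 18 in replicate 2, while the combined list had 0 there. These peaks covered 63.3% and 48.02% of the mitochondrial genome, whose length was taken as the largest peak end, 13421 bp. The best of them was peak number 543 in replicate 1 and number 173 in replicate 2. No value for the input samples was at hand to set beside them. Arbitrary placement along the genome is argued against: 13 of the 18 replicate 2 peaks had a replicate 1 midpoint within 100 bp, against a mean of 6.47 over all 13421 circular offsets. Only 0.611% of the offsets reached 13, all of them within 100 bp of no shift, and larger offsets reached at most 11. Neighbouring offsets are not independent, so this share is not a p-value. Of 16 overlapping pairs of mitochondrial peaks, 12 ranked within the first 6494 peaks in both replicates. Those ranks held 14 mitochondrial peaks of replicate 1 and 15 of replicate 2, and the combined list had 0. Among all of the first 6494 peaks, 90.6% of replicate 1 and 89.1% of replicate 2 overlapped a combined peak, while 609 and 709 did not. For the 12 pairs, these values argue against a low rank in the replicate lists as the reason for their absence. The rule of the combined list is not known, so whether they scored low under that rule cannot be decided. A removal of mitochondrial peaks by the authors, reads from abundant mitochondrial DNA that repeat the same uneven coverage, and binding there all stay open and were not tested, and no biological explanation was tested.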

How the results depend on the processing

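Of 66 comparisons of a result with an alternative, 64 kept their direction and their side of the threshold. Most concern overlaps or correlations, where every p-value was the smallest its resampling can give, so the count says little about them. For the density on X, 7 of 9 alternatives kept the result, and there this meant staying above the threshold. The alternatives added after seeing the data were the lower-ranked 3247 combined peaks, the ranking by peak number, the lists without mitochondrial peaks, the shifts of 5 to 50 kb and the permuted blocks of 1 Mb. The exceptions concern the density on X against the autosomes: with the 3247 higher-ranked combined peaks the ratio of 1.04 became 0.82, and with the 3247 lower-ranked ones it rose to 1.28 and passed the threshold. Both sets come from the same list and differ in rank. Explanations of this difference are weighed in the last part, and no biological one was tested. To leave 1 replicate out, the nuclear peaks among the first 6494 of the other replicate's own list replaced the combined list, which was not remade. The ratio on X was then between 1.005 and 1.05, by either ranking, and that of the autosomal centres was between 1.68 and 1.77. Over all alternatives the ratio in the centres was between 1.52 and 1.86. A permutation test over 1 Mb blocks gave p = 1e-05 for the centres, the smallest possible, and p = 0.68 for X. Blocks were permuted only for the whole combined list, not for its higher-ranked or lower-ranked peaks. The overlap of equally long lists was lowest, at 65.8% for replicate 1 and 67.1% for replicate 2, when the lists held 3247 peaks. With a 50% reciprocal overlap, 83.7% of combined peaks were matched in both replicates. Shifts of only 5 to 50 kb raised the chance overlap of equally long lists to 6.28% and 6.36%. Spearman's rho fell to 0.51 and Pearson's r to 0.30 in the upper 50% of the pairs. These pairs span a narrower range of ranks, and 3191 peaks of replicate 1 and 1783 of replicate 2 share their list's highest score. Both can lower a correlation, and neither was tested as the cause. Overlap and score agreement need both replicates, so leaving one out gives no value for them. No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, had no list here. The tests of peaks near gene starts and of gene lists were not run, and neither were their alternatives. Read depth is unknown, so a peak seen in only 1 replicate cannot be read as a difference in binding.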

Other observations

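Of the tests in this part, the comparison of X shares between higher and lower ranks was chosen after the shares had been seen, and the tests of its explanations were set before their results were seen. Several long regions held no combined peak, a description made after the lists were examined. The longest lay on the right part of chromosome V, from 16965961 to 17857874, a stretch of 892 kb. Even spacing along that chromosome would place 39.8 combined peaks in it. The right 33.3% of V, which includes this stretch, had 30.5 combined peaks per Mb against 44.6 over all of V. Even spacing within that part would therefore place fewer. The replicates were sparse in this stretch too, with 44 and 26 peaks where 203 and 166 would be expected from their mean density on V. Of these peaks, 0 ranked among the first 6494 in either. The left end of X was similar: the first combined peak began at 324028, where even spacing would give 21.7 peaks before it, and the replicates had 24 and 15 peaks in place of 113 and 91.3. On chromosome II no combined peak lay between 1520296 and 1808175, a stretch of 288 kb. The densest windows of 100 kb were on chromosome II at 6820001 to 6920000 with 32 combined peaks and on chromosome I at 7460001 to 7560000 with 31, against a genome mean of 6.48. Further down the ranks, the replicate lists held fewer of their autosomal peaks in the middle part, and in replicate 1 the share fell below that of the length, 33.3%. The share of autosomal peaks in the middle part was 44.9% in the highest-ranked 10% of replicate 1 and 28.7% in the lowest-ranked 10%, and 46.2% and 36.7% in replicate 2.

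The share of peaks on X rose down the ranks of the combined list, and in the replicate lists it rose and then fell in part. In replicate 1 it was 14.2% in the highest-ranked 10%, at most 23.6% in any later 10%, and 21.2% in the last, and in replicate 2 these values were 16.4%, 24.8% and 20.4%. In the combined list X held 21.6% (20.2 to 23.1%) of the 3247 lower-ranked peaks and 14.9% (13.7 to 16.2%) of the 3247 higher-ranked peaks (Fisher's exact test, two-sided, odds ratio 1.57, p = 3.6e-12). Chromosome X had 1.45 times as many lower-ranked as higher-ranked peaks, while the autosomes ranged from 0.77 on III to 1.06 on IV. In the replicate lists, calls that the other replicate does not repeat are argued against as the whole cause. Among peaks ranked 3248 to 12988, repeated ones were on X in 22.7% of cases in replicate 1 and 21.99% in replicate 2. These shares were above the 14.5% and 17.4% of the higher ranks, with 95% intervals that did not overlap. Unrepeated peaks of the same ranks were on X in 21.9% (20.1 to 23.8%) and 23.2% (21.2 to 25.4%) of cases. In the combined list 6456 of 6494 peaks shared at least 1 bp with the full lists of both replicates, so few were unrepeated by that rule. With a 50% reciprocal overlap, 83.7% were matched in both. The combined list was made from the same samples, so this overlap does not test the explanation there. A few domains of X are argued against as well, since 15 of its 18 bins of 1 Mb held more lower-ranked than higher-ranked peaks. A candidate explanation that stays open is a difference of X in read coverage, base composition or mappability, which these lists cannot test. No biological explanation was tested.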
